A study of Homo sapiens with 12 samples.

How the data were processed

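RNA sequencing was done on 12 libraries of primary human umbilical vein endothelial cells, 3 per time (0, 5, 10 and 30 min under flow), each from an independent experiment in which plates were pooled per time, per the labels. Per the labels' protocols, RNA was extracted with a column kit and made into stranded libraries with a dUTP second strand. Per the submitters' processing notes, the authors trimmed reads with cutadapt, aligned them to GRCh37 with HISAT2 and quantified genes with StringTie; versions are not given in the sources used here.

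The authors deposited FPKM values per gene and library, in a table of 12494 protein-coding genes. The authors also deposited 3 comparison tables, each flow time against 0 min, with a log2 fold change, a linear fold, and p-values and q-values per gene. The log2 values in the group columns of these tables, although headed FPKM per the file headers, equalled the mean of log2(FPKM + 1) of each group, and the test behind the deposited p-values is not stated in the sources used here. Read counts were not used here, so depth is unknown. Low FPKM values were checked for steps worth 1 read, and none were found (at most 1.80% of genes with a mean FPKM under 1.5 fell in the fullest bin of any library).

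From the deposited FPKM, log2(FPKM + 1) was computed, and a fold change here is on that scale, which understates the change of genes with low FPKM. Genes that mark the donor were left out (8 genes, leaving 12486), and 10799 genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested. The main test was limma with a mean-variance trend (limma 3.58.1 in R 4.3.3) on all 12 libraries in 1 fit with 4 groups and no further covariate, two-sided, with Benjamini-Hochberg adjustment at 0.05. The fit had 8 residual degrees of freedom and 4.50 prior degrees of freedom, and the median standard error of a log2 change was 0.315. Each flow time was compared with 0 min and with the other flow times, and an F test covered all groups. A change was called where the adjusted p was under 0.05.

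Of 35 gene lists, 32 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation, and fry, were run beside it. Genes named in the text followed a fixed rule. Against 0 min these were the 10 largest changes in each direction among called genes with a symbol, a group mean FPKM of at least 1 and libraries that did not overlap, filled up to 5 by smallest p where fewer passed. Between flow times these were 5 per direction, filled up to 2. Added to them were the 4 members of smallest p in each list and 11 genes named in advance. Genes with only a clone name were counted and not named. The tests, comparisons, lists, naming rule and alternatives except the 3 named below were chosen before the data were examined.

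The alternatives were a pseudocount of 0.1 or 0.01, no filter or a mean FPKM of at least 5, median-of-ratios rescaling, FPKM rescaled to the same total in every library, quantile normalization, the replicate number as a block, a fit of only the groups compared, array weights, robust empirical Bayes, removal of mitochondrial, ribosomal protein and histone genes, and leaving out each library and each replicate number. After the data were seen, 3 more were added: leaving out both libraries with the most alpha-globin, alpha-globin as a covariate, and removal of a trend with transcript length by lowess. Transcript lengths came from GENCODE v29 on GRCh38, matched by Ensembl number for 12315 of the 12486 genes (98.6%), and no coordinates were taken from it. Coordinates in the text are those of the deposited files, on GRCh37.

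Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The fit was tested on simulated data for 5 min against 0 min with 10799 genes over 10 runs. It called 22.8%, 79.6%, 93.6% and 98.2% of genes changed by 1, 2, 3 and 4 on the log2 scale, 0 with the wrong sign, and 102 unchanged genes in all runs together. A shifted list was recovered, and 0 other lists were called. The simulated noise was independent between genes, so this cannot show false list calls that arise where genes move together. Comparisons that share the 0 min libraries were set against 100 simulations of unchanged groups, made by reassigning the residuals of all 12 libraries. Levels of genes that mark the donor are not reported here.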

Results

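Gene expression was measured by RNA sequencing in primary human umbilical vein endothelial cells (HUVECs, the endothelial lining of the umbilical vein). The cells had been cultured overnight on fibronectin-coated dishes and then exposed to laminar shear of 15 dyn/cm2 in a parallel plate flow chamber. The 0 min group was the whole population, and the 5, 10 and 30 min groups were the cells still adherent after that time under flow. Each of the 4 groups had 3 libraries from independent experiments, 12 in all. The deposited FPKM values, which are fragment numbers scaled to transcript length and depth, listed 10872 to 12007 genes above 0 per library. Sequencing depth is unknown, since the values used here were not counts. The question was which genes differed between the cells that stayed attached and the whole population.

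Alpha-globin transcripts (HBA1 and HBA2, the red cell oxygen carrier) were at a summed FPKM of 0.187 to 1.03 in the 0 min libraries. They reached 315, 96.3 and 49.6 in the 10 min libraries, 283, 12.6 and 11.7 in the 30 min libraries, and 10.2, 6.47 and 43.2 in the 5 min libraries (replicates 1, 2 and 3). The median of 47 endothelial identity genes lay 1.88 below the 0 min mean on the log2 scale in 10 min replicate 1 (−1.88) and at −0.89 in 30 min replicate 1. It lay at −0.27 and −0.24 in 10 min replicates 2 and 3 and between −0.14 and 0.13 in the other 8 libraries. The first principal component held 41.4% of the variance and set 10 min replicate 1 (score 87.1) and 30 min replicate 1 (54.0) apart from the others (−32.3 to 19.3). Correlations between libraries of the same group were 0.952 to 0.975 at 0 min, 0.937 to 0.962 at 5 min, 0.810 to 0.932 at 10 min and 0.853 to 0.970 at 30 min. The 13 mitochondrially encoded genes held 7.08% (5 min replicate 1) to 33.6% (10 min replicate 1) of the summed FPKM. In a check for mixed-up samples, 0 of 12 libraries departed from most of their own group, but 6 libraries did not match the other 6. The groups therefore did not all come from the same donor or donor pool, and donor and time cannot be told apart for some of the comparisons below. A gene said below to rise or fall differed between groups, and donor as well as time may lie behind the difference.

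**Figure D1:**
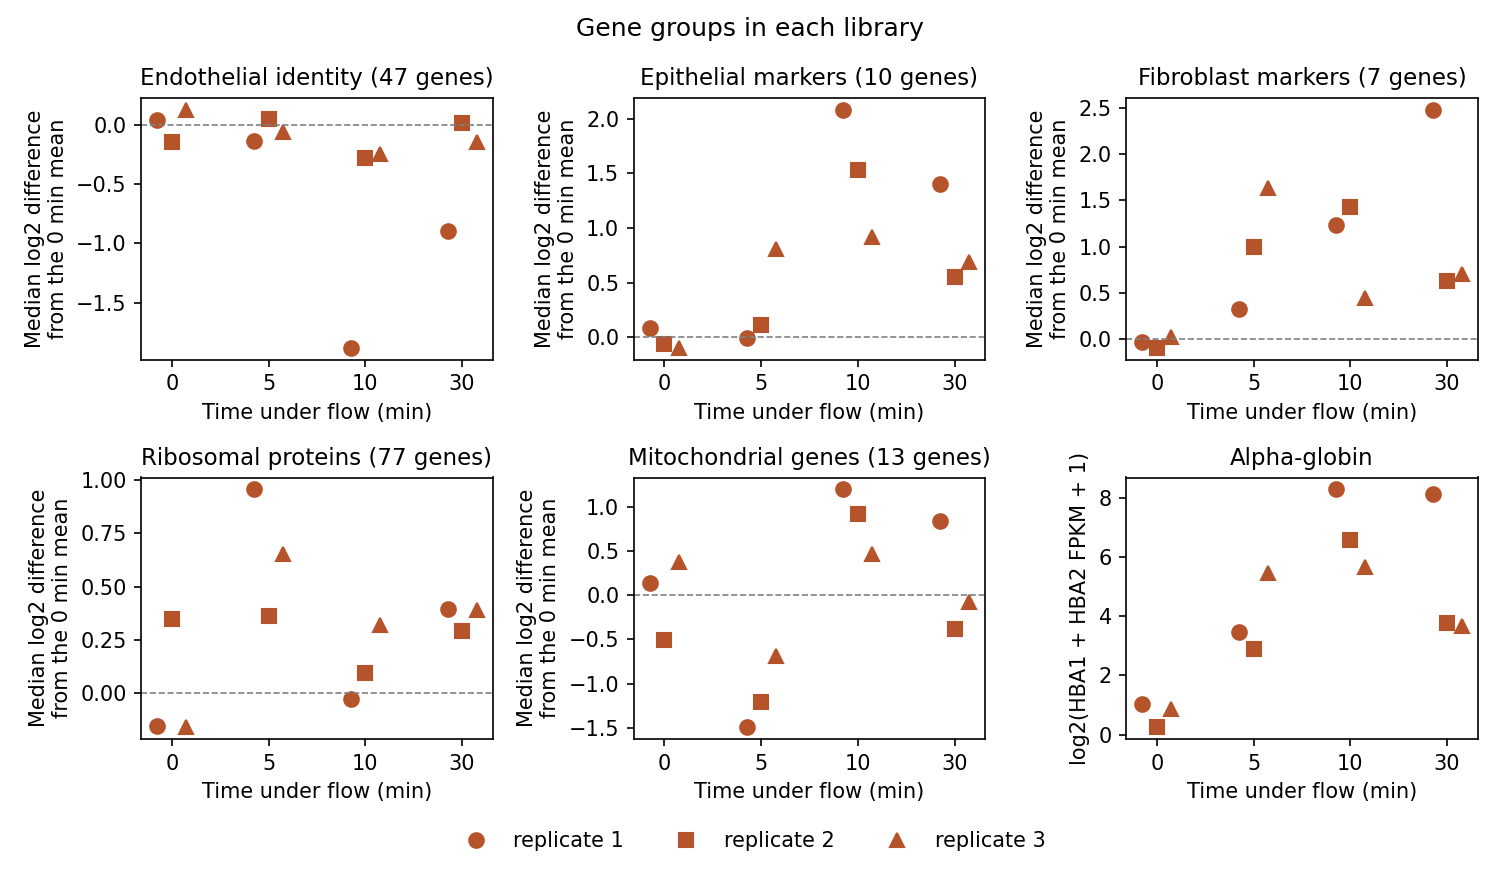
Medians of 5 groups of genes as log2 difference from the 0 min mean, and alpha-globin as log2(HBA1 + HBA2 FPKM + 1), against time under flow in min, with 1 marker per library. The replicate 1 libraries at 10 and 30 min had the lowest endothelial medians (−1.88 and −0.89) and the highest alpha-globin FPKM (315 and 283). Among the rescalings tried, only quantile normalization took away the higher mitochondrial level at 10 min. With alpha-globin as a covariate that level also reversed (median −0.54), without passing the threshold.

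At 5 min, transcripts of SERPINB2 (plasminogen activator inhibitor 2, which limits cleavage of matrix and fibrin) and DOK5 (an adaptor for receptor tyrosine kinases) rose. SERPINB2 was at an FPKM of 47.9 ± 6.80 (SD, n = 3) at 5 min and 6.01 ± 2.90 at 0 min, a log2 change of 2.87 ± 0.48 (SE; adjusted p = 0.0362, limma with Benjamini-Hochberg adjustment). DOK5 went from 1.16 ± 0.28 to 9.76 ± 2.38 (log2 change 2.30 ± 0.34, limma adjusted p = 0.0262). SPATC1L was listed at 0 in all 3 libraries at 0 min and at 7.73 ± 1.63 at 5 min (limma adjusted p = 0.00451), and SMOC2, an extracellular calcium-binding protein, was listed at 0 and at 3.15 ± 0.34 (limma adjusted p = 0.0184). The membrane scaffold FLOT2 (1.63 ± 0.25, adjusted p = 0.0262), the sugar dehydrogenase CRYL1 (1.75 ± 0.24, adjusted p = 0.0184) and PNMA2 (1.69 ± 0.26, adjusted p = 0.0262) also rose by limma. Higher by the same test were the antiviral IFITM1 (2.15 ± 0.36), the lipid enzymes PLA2G16 (1.96 ± 0.34) and FAM213B (1.92 ± 0.32) and the ribosomal protein RPL36 (1.13 ± 0.18), at limma adjusted p of 0.0362, 0.0416, 0.0362 and 0.0305.

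The growth factor TGFB2 and the microfibril protein FBN2 fell at 5 min. TGFB2 was at 2.66 ± 0.48 (SD, n = 3) at 5 min and 21.3 ± 4.98 at 0 min (log2 change −2.59 ± 0.44, limma adjusted p = 0.0416), and FBN2 at 3.06 ± 0.54 and 15.3 ± 1.04 (−2.01 ± 0.25, limma adjusted p = 0.00846). GPD2, the mitochondrial glycerol-3-phosphate dehydrogenase, fell from 8.89 ± 2.31 to 1.65 ± 0.22 (−1.88 ± 0.28, limma adjusted p = 0.0262). ADA2, a secreted adenosine deaminase, fell by 1.98 ± 0.31 (limma adjusted p = 0.0305). The mitochondrial transcripts MT-CYB (cytochrome b; 904 ± 142 against 2685 ± 689) and MT-ND5 (complex I) both fell by 1.55 (limma adjusted p = 0.0262 and 0.0362). C15orf38-AP3S2, a readthrough transcript, was at 8.08 ± 0.89 at 0 min and was listed at or near 0 at 5 min (limma adjusted p = 3.42e-05). It overlaps AP3S2, which went the other way (0.893 ± 0.135 at 0 min and 3.49 ± 0.17 at 5 min), so how reads were split between these genes is uncertain.

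In all, 11 genes were higher and 7 lower at 5 min by limma, each with all 3 libraries on the same side of all 3 at 0 min, and 1155 genes (656 higher, 499 lower) had an unadjusted p under 0.05. The libraries of both groups did not overlap for 3061 genes, 28.3% of the 10799 tested (chance gives 10%). On GRCh37, SERPINB2 (ENSG00000197632.8_3) lies on chromosome 18 at 61538926 to 61571124 and DOK5 (ENSG00000101134.11_2) on chromosome 20 at 53092136 to 53267710. SPATC1L (ENSG00000160284.14_2) lies on chromosome 21 at 47581062 to 47604390. TGFB2 (ENSG00000092969.11_2) lies on chromosome 1 at 218519577 to 218617961 and FBN2 (ENSG00000138829.11_3) on chromosome 5 at 127593601 to 127994878. C15orf38-AP3S2 (ENSG00000250021.7_4) lies on chromosome 15 at 90377540 to 90456114. Of the 17 genes named here by their size, SPATC1L alone stayed called in all 12 fits that left out 1 library. C15orf38-AP3S2 stayed called in the 9 fits that tested it, but without any 1 of the 0 min libraries it fell under the filter on low values and was not tested. Calls higher and lower numbered 1 and 1, 5 and 4, and 2 and 0 without 0 min replicates 1, 2 and 3. They numbered 1 and 1, 4 and 2, and 1 and 1 without 5 min replicates 1, 2 and 3, 28 and 20 without 10 min replicate 1, 17 and 9 without 30 min replicate 1, and 7 and 5 without 30 min replicate 2 or 3.

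**Figure D2:**
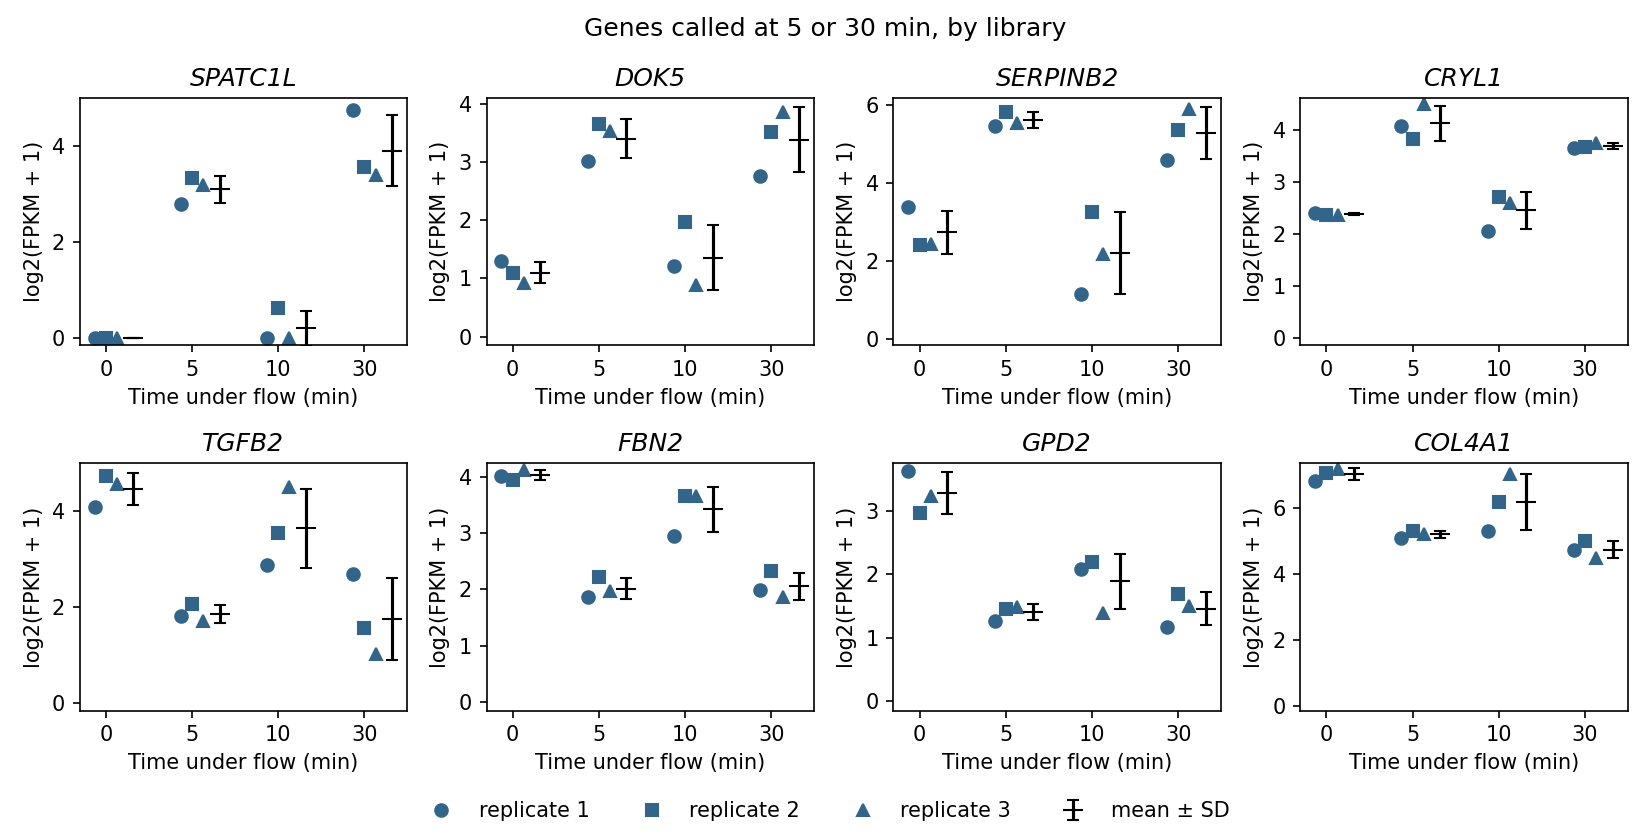
Expression of 8 genes called at 5 or 30 min as log2(FPKM + 1) against time under flow in min, with 1 marker per library shaped by replicate, and the mean ± SD of each group (n = 3). SPATC1L was listed at 0 in every 0 min library and averaged 7.73 FPKM at 5 min, 0.183 at 10 min and 15.5 at 30 min.

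All 77 ribosomal protein genes had a positive log2 change at 5 min, with a median of 0.67 (camera with a preset correlation, adjusted p = 7.78e-30; adjusted p = 0.344 with an estimated correlation). RPL36 alone rose over all genes, and 42 rose adjusted over the list alone. RPS28 had the largest change among the 4 members of smallest p (2.14 ± 0.44, limma adjusted p = 0.106, not past the threshold). Of the nuclear genes for oxidative phosphorylation, 66 of 74 were positive (median 0.39, camera adjusted p = 5.01e-09; adjusted p = 0.42 with an estimated correlation), with ATP5D, an ATP synthase subunit, at 1.18. The 13 mitochondrially encoded genes went the other way, 12 of 13 negative with a median of −0.95 (camera adjusted p = 4.07e-08; adjusted p = 0.545 with an estimated correlation). Of these, 2 fell over all genes, and 9 fell and 1 rose adjusted over the list alone. The 0 min libraries themselves spread on these groups: 0 min replicate 2 had a ribosomal median of 0.35 and a mitochondrial median of −0.51, against −0.16 and 0.13 in replicate 1.

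Mitotic genes were lower at 5 min (51 of 65 negative, median −0.26; camera adjusted p = 0.00045, and 0.815 with an estimated correlation). The spindle checkpoint kinase BUB1 was at −0.74 and the mitotic kinesin KIF20A at −0.81. Glycolytic and hypoxia genes were higher (26 of 33 positive, median 0.17; camera adjusted p = 0.00347, and 0.344 with an estimated correlation). The glycolytic enzymes TPI1 and GAPDH were at 0.63 and 0.58. Fibroblast markers were higher (6 of 7 positive, median 0.90; camera adjusted p = 0.00565, and 0.545 with an estimated correlation). The collagens COL1A1 and COL3A1 were at 2.26 and 1.48. In 5 min replicates 1, 2 and 3 the fibroblast median was 0.33, 1.00 and 1.64, the epithelial median −0.01, 0.11 and 0.81 and alpha-globin FPKM 10.2, 6.47 and 43.2. Immediate early genes were higher (29 of 43 positive, median 0.34; camera adjusted p = 0.0449, and 0.815 with an estimated correlation). The phosphatase DUSP5 was at 1.41 and the transcription factor MAFF at 1.56. No gene of these 4 groups passed the threshold over all genes, and adjusted over the list alone 1 fibroblast marker rose and none of the others changed. The mitotic call was lost without 5 min replicate 3 (median −0.13, adjusted p = 0.0929). The immediate early call was lost without 0 min replicate 1 (adjusted p = 0.0796) or 2 (0.206) and without 5 min replicate 2 (0.157) or 3 (0.133). With alpha-globin as a covariate, chosen after the data were seen, 3 of the 7 list calls at 5 min were kept, and the immediate early median reversed without passing (−0.24, adjusted p = 0.214). The mitotic, hypoxia and fibroblast calls were lost as well. Over all alternatives the adjusted p lay between 3.81e-09 and 0.906 for the mitotic genes and between 0.00257 and 0.815 for the immediate early genes.

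At 10 min, C15orf38-AP3S2 was the only gene past the threshold (listed at or near 0 against 8.08 ± 0.89 at 0 min, SD, n = 3; limma with Benjamini-Hochberg adjustment, adjusted p = 3.42e-05), with the same uncertainty against AP3S2, which averaged 2.61 ± 0.19 at 10 min. Without 0 min replicate 1, 2 or 3 the gene fell under the filter on low values and limma called 0 genes at 10 min. The same held with a mean FPKM of at least 5, and with a pseudocount of 0.01 it did not pass (adjusted p = 0.233; 4.85e-07 to 0.233 over the alternatives that tested it). No gene was called higher by limma, although 1743 (995 higher, 748 lower) had an unadjusted p under 0.05 and the pooled-variance test of the authors' deposited table gave 10 at q under 0.05. The libraries of both groups did not overlap for 2596 genes, 24.0% (chance gives 10%). Among genes that did not pass, the acute phase protein SAA1 averaged 235 ± 174 at 10 min and 0.609 at 0 min (log2 change 6.92 ± 1.13), and the calcium-binding S100A4 averaged 204 ± 174 and 1.13 (6.26 ± 1.00), both at limma adjusted p = 0.0712. The protease inhibitor SLPI (5.38 ± 0.91), the lens and stress chaperone CRYAB (5.61 ± 0.96), the Toll-receptor cofactor LY96 (−3.09 ± 0.48) and the Notch transcription factor RBPJ (−1.28 ± 0.22) stood at the same limma adjusted p of 0.0712. Without 10 min replicate 3, limma called 112 genes higher and 39 lower, without 30 min replicate 1 it called 122 and 23, and without 5 min replicate 3 it called 15 and 3. SAA1 then passed in each of these cases (adjusted p = 0.0215, 0.0114 and 0.029; 0.0016 to 0.776 over all alternatives), as did S100A4, SLPI, CRYAB and LY96. The calls were 1 and 1 without 5 min replicate 2, 1 and 2 without 10 min replicate 1, and 0 and 2 without 10 min replicate 2. LY96 passed without 10 min replicate 1 (0.0093) or 2 (0.045), and RBPJ without 10 min replicate 3 (0.0406) or 30 min replicate 1 (0.0184). Over all alternatives the log2 change lay between 0.81 and 9.30 for SAA1 and between 0.92 and 7.40 for S100A4. It lay between 0.48 and 8.66 for SLPI and between 0.22 and 7.36 for CRYAB, so these sizes depended on the setting. Whether these genes followed alpha-globin from library to library was not tested.

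Endothelial identity genes were lower at 10 min, 44 of 47 negative with a median of −0.74 (camera with a preset correlation, adjusted p = 1.07e-07; adjusted p = 0.664 with an estimated correlation). None passed over all genes and 2 fell adjusted over the list alone. The surface sialomucin CD34 was at −1.03 (limma adjusted p = 0.0944) and the diaphragm protein PLVAP at −1.74. Epithelial markers were higher in the same libraries, 9 of 10 positive with a median of 1.25 (camera adjusted p = 0.000107, and 0.409 with an estimated correlation). Of these, 5 rose adjusted over the list alone. The adhesion protein EPCAM was at 2.04 and the keratin KRT8 at 2.63. Fibroblast markers had a median of 1.22 with 5 of 7 positive and 3 rising adjusted over the list alone (camera adjusted p = 0.0131, and 0.664 with an estimated correlation). COL1A1 was at 3.24. HBA1 was at 5.98 (limma adjusted p = 0.0802), and the 4 measured genes of erythroid cells and platelets, too few for the list test, had a median of 3.95 and all rose adjusted over the list alone. The epithelial median was 2.08, 1.53 and 0.92 in 10 min replicates 1, 2 and 3, where alpha-globin was at 315, 96.3 and 49.6. The endothelial median was −1.88, −0.27 and −0.24 in these libraries. The fibroblast median, at 1.24, 1.43 and 0.45, did not keep the order of alpha-globin. With 10 min replicate 1 and 30 min replicate 1 left out, a choice made after the data were seen, the 10 min endothelial median was −0.25 (camera adjusted p = 0.00366) and the epithelial median 1.11 (0.00151). With alpha-globin as a covariate, also chosen after the data were seen, 11 of the 13 lists called at 10 min reversed, and the endothelial genes passed the threshold in the other direction (median 0.71, camera adjusted p = 0.000617). Alpha-globin was low in all 0 min libraries, so that covariate partly stands for flow itself. The adjusted p over all alternatives, in either direction, lay between 9.69e-11 and 0.664 for the endothelial genes and between 8.51e-07 and 0.985 for the epithelial genes.

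NF-kB and inflammatory genes were higher at 10 min, 22 of 32 positive with a median of 0.42 and 8 rising adjusted over the list alone (camera adjusted p = 0.00366, and 0.664 with an estimated correlation). The coagulation starter F3 was at 5.79 (limma adjusted p = 0.0827) and the chemokine CCL20 at 4.68. Immediate early genes had a median of 0.30 with 28 of 43 positive and 4 rising adjusted over the list alone (camera adjusted p = 0.0028, and 0.664 with an estimated correlation). The transcription factor EGR1 averaged 65.4 ± 69.2 against 2.26 ± 0.59 at 0 min (3.81, limma adjusted p = 0.107). In 10 min replicates 1, 2 and 3, where alpha-globin was at 315, 96.3 and 49.6, the NF-kB median was 0.95, 0.47 and 0.42 and the immediate early median 0.80, 0.57 and 0.20. With alpha-globin as a covariate both lists passed the threshold in the other direction (medians −0.76 and −0.43, camera adjusted p = 0.000617 and 0.0265; 0.00015 to 0.664 and 0.000184 to 0.664 over all alternatives). Cholesterol synthesis genes were higher (27 of 33 positive, median 0.39, 2 rising adjusted over the list alone; camera adjusted p = 0.00224, and 0.664 with an estimated correlation). Hypoxia and glycolysis genes were higher too (24 of 33, median 0.25; camera adjusted p = 0.0104, and 0.409 with an estimated correlation). The 13 mitochondrially encoded genes were all positive with a median of 0.81 and 5 rising adjusted over the list alone (camera adjusted p = 7.11e-07, and 0.664 with an estimated correlation), but under quantile normalization the median was −0.05 (adjusted p = 0.872). Ribosomal protein genes had a median of 0.13 (53 of 77 positive; camera adjusted p = 0.0357, and 0.865 with an estimated correlation), which became −0.10 (adjusted p = 0.433) with FPKM rescaled to the same total in every library. That rescaling moved the median of all genes to −0.27, from −0.03 in the values as deposited. Other lists also kept the order of alpha-globin over 10 min replicates 1, 2 and 3. Their medians were 1.20, 0.92 and 0.47 (mitochondrial), 0.55, 0.49 and 0.16 (cholesterol), and 0.43, 0.25 and 0.18 (hypoxia). With alpha-globin as a covariate these medians reversed without passing (−0.54, −0.49 and −0.02). The ribosomal call was also lost without 0 min replicate 1 (0.576) or 3 (0.397) or 10 min replicate 3 (0.616), and the hypoxia call without 10 min replicate 1 (0.0507). Over all alternatives the adjusted p lay between 3.58e-09 and 0.872 (mitochondrial), 5.07e-07 and 0.978 (ribosomal), and 0.00377 and 0.667 (hypoxia).

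Lower at 10 min were Notch genes (21 of 27 negative, median −0.44; camera adjusted p = 0.00326, and 0.664 with an estimated correlation), with the Notch target HEY2 at −1.54. VEGF and angiogenesis genes were lower as well (29 of 40, median −0.47; camera adjusted p = 0.0121, and 0.664 with an estimated correlation), with the vessel destabiliser ANGPT2 at −1.18. Lower too were mitotic genes (50 of 65, median −0.32; camera adjusted p = 0.0028, and 0.673 with an estimated correlation), with the kinetochore protein SPC25 at −1.16. The p53 targets were lower (24 of 32, median −0.40; camera adjusted p = 0.0153, and 0.673 with an estimated correlation), with the RNA-binding ZMAT3 at −1.07. Adjusted over the list alone, 1 Notch gene and 1 VEGF gene fell and no gene of the others did. The Notch median was −0.83, −0.23 and −0.13 and the mitotic median −0.42, −0.11 and −0.25 in 10 min replicates 1, 2 and 3, the first with the most alpha-globin. With alpha-globin as a covariate, chosen after the data were seen, these medians reversed without passing (Notch 0.11, VEGF 0.12, mitotic 0.25, p53 0.40). The p53 call was lost without 0 min replicate 2 (0.0909) or 10 min replicate 1 (0.107), and the VEGF call without 0 min replicate 3 (0.0663) or 10 min replicate 1 (0.129). Over all alternatives the adjusted p lay between 0.00271 and 0.673 (p53) and between 0.00377 and 0.984 (VEGF). With both libraries with the most alpha-globin left out, a choice made after the data were seen, the VEGF median was −0.12 (adjusted p = 0.183) and the p53 median −0.13 (0.0989).

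At 30 min, DOK5 and SPATC1L were again higher than in the whole population and TGFB2, FBN2, GPD2 and C15orf38-AP3S2 again lower. DOK5 averaged 9.93 ± 3.89 (SD, n = 3; log2 change 2.28 ± 0.34, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0286). SPATC1L averaged 15.5 ± 9.21 against a listing of 0 in every 0 min library (limma adjusted p = 0.000343). The mitochondrial ribosome chaperone ERAL1 (1.60 ± 0.27, adjusted p = 0.0469), the nucleotide hydrolase NUDT2 (1.59 ± 0.24, adjusted p = 0.0286) and the clathrin light chain CLTB (1.21 ± 0.20, adjusted p = 0.0469) rose by limma. COL4A1, a basement membrane collagen (ENSG00000187498.14_3, chromosome 13, 110801310 to 110959496), fell from 131 ± 16.9 to 25.8 ± 4.78 (−2.31 ± 0.34, limma adjusted p = 0.0284), and its partner COL4A2 was at −1.36 (limma adjusted p = 0.0605). CD34 (ENSG00000174059.16_4, chromosome 1, 208054317 to 208084747) fell from 8.86 ± 2.25 to 2.47 ± 0.18 (−1.48 ± 0.22, limma adjusted p = 0.0284). TGFB2 was at −2.70 ± 0.44 (limma adjusted p = 0.0463), FBN2 at −1.97 ± 0.25 (0.0106), GPD2 at −1.83 ± 0.28 (0.0286) and C15orf38-AP3S2, uncertain against AP3S2 (4.37 ± 1.87), again at or near 0 (3.42e-05). The membrane proteins ITM2A (−2.15 ± 0.29) and AMPH (−1.70 ± 0.27), the latter an endocytosis factor, fell at limma adjusted p of 0.0203 and 0.0363.

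By limma 5 genes were higher and 8 lower at 30 min, and 1104 (623 higher, 481 lower) had an unadjusted p under 0.05. The libraries of both groups did not overlap for 2424 genes, 22.4% (chance gives 10%). Of these 13 genes, SPATC1L alone stayed called in all 12 fits that left out 1 library. C15orf38-AP3S2 stayed called in the 9 fits that kept all 0 min libraries and was not tested in the other 3. Calls higher and lower numbered 1 and 0, 2 and 0, and 1 and 0 without 0 min replicates 1, 2 and 3, and 1 and 2, and 1 and 1, without 30 min replicates 2 and 3. They numbered 1 and 3, and 2 and 3, without 5 min replicates 1 and 2, 8 and 8 without 5 min replicate 3, and 27 and 42 without 10 min replicate 1. With 10 min replicate 3 left out, 4 were higher and 12 lower. A pseudocount of 0.01 gave 0 calls, and quantile normalization gave 39.

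Ribosomal protein genes were higher at 30 min, 69 of 77 positive with a median of 0.34 and 2 rising adjusted over the list alone (camera with a preset correlation, adjusted p = 8.01e-10; adjusted p = 0.576 with an estimated correlation), with RPS2 at 1.27 (limma adjusted p = 0.0605). Nuclear oxidative phosphorylation genes had a median of 0.20 (51 of 74 positive; camera adjusted p = 0.0118, and 0.744 with an estimated correlation). Cholesterol synthesis genes had a median of 0.23 (26 of 33; camera adjusted p = 0.022, and 0.697 with an estimated correlation), with the synthase HMGCS1 at 1.07. Fibroblast markers were positive in 7 of 7 genes (median 1.13, 2 rising adjusted over the list alone; camera adjusted p = 0.00123, and 0.498 with an estimated correlation), with COL1A1 at 3.23. Epithelial markers were positive in 8 of 10 (median 0.83, 1 rising adjusted over the list alone; camera adjusted p = 0.0118, and 0.498 with an estimated correlation), with the keratin KRT19 at 2.14. The fibroblast median was 2.48 in 30 min replicate 1, which had an alpha-globin FPKM of 283, against 0.62 and 0.70 in replicates 2 and 3. The oxidative phosphorylation call was lost without 0 min replicate 1 (0.223) or 3 (0.151) or 30 min replicate 1 (0.0883), and without 30 min replicate 1 the cholesterol (0.529) and epithelial (0.0883) calls were lost. Their adjusted p over all alternatives lay between 4.25e-07 and 0.744 (oxidative phosphorylation), 0.00369 and 0.697 (cholesterol), and 0.000303 and 0.678 (epithelial).

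Notch genes were lower at 30 min (21 of 27 negative, median −0.45; camera adjusted p = 0.000361, and 0.498 with an estimated correlation), with the ligand JAG1 at −0.96 and the arterial marker EFNB2 at −1.04. TGF-beta and BMP genes had a median of −0.21 (31 of 42 negative; camera adjusted p = 0.00526, and 0.576 with an estimated correlation), TGFB2 falling over all genes and 4 genes adjusted over the list alone, with the receptor BMPR2 at −1.44. Endothelial identity genes had a median of −0.38 (36 of 47 negative; camera adjusted p = 0.00297, and 0.866 with an estimated correlation), with CD34 falling over all genes and adjusted over the list alone. VEGF and angiogenesis genes (26 of 40 negative, median −0.35, 2 falling adjusted over the list alone; camera adjusted p = 0.0119, and 0.626 with an estimated correlation) included ANGPT2 at −1.38 and the guidance ligand SLIT2 at −1.20. The p53 targets (26 of 32 negative, median −0.35; camera adjusted p = 0.00705, and 0.626 with an estimated correlation) included the cell cycle inhibitor CDKN1A at −0.77. With alpha-globin as a covariate, 1 of the 10 list calls at 30 min (ribosomal) was kept. The endothelial genes then passed in the other direction (median 0.81, camera adjusted p = 1.98e-05), and the p53 (0.19), cholesterol (−0.31) and epithelial (−0.33) medians reversed without passing (adjusted p = 0.249, 0.113 and 0.678). Without 30 min replicate 1 the endothelial median was −0.07 (adjusted p = 0.28) and the p53 call was lost (0.192). That library was also lowest for Notch genes (−0.77, −0.43 and −0.21 in replicates 1, 2 and 3) and TGF-beta genes (−0.55, −0.15 and −0.13), though both calls were kept without it. The p53 call was lost without 0 min replicate 2 (0.057), and the TGF-beta and VEGF calls without 0 min replicate 3 (0.105 and 0.0625). Over all alternatives the adjusted p lay between 1.98e-05 and 0.866 (endothelial), 0.00035 and 0.626 (p53), 0.000231 and 0.678 (TGF-beta), and 0.00295 and 0.787 (VEGF).

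Genes fixed for reporting in advance because flow or adhesion involves them did not pass the threshold against 0 min at any time, although some did under an alternative. The flow-induced transcription factor KLF2 was at 1.46, −0.23 and 0.17 at 5, 10 and 30 min (limma with Benjamini-Hochberg adjustment, adjusted p = 0.197, 0.769 and 0.883), KLF4 at 0.44, 1.00 and 0.58 and the nitric oxide synthase NOS3 at 0.83, −0.57 and 0.61. EGR1 was at 1.90, 3.81 and 2.65 (limma adjusted p = 0.451, 0.107 and 0.319) and FOS, also an early response factor, at 1.13, 3.24 and 2.46. Fibronectin (FN1) averaged 262 ± 55.0 at 0 min (SD, n = 3), 141 ± 6.55 at 5 min and 112 ± 6.95 at 30 min (−0.86 and −1.20, limma adjusted p = 0.22 and 0.0666). The fibronectin receptor subunits ITGA5 (−0.05, −0.60 and −0.29) and ITGB1 (−0.08, −0.29 and −0.28), the junction cadherin CDH5 (0.43, −0.13 and −0.18) and VWF (0.15 and −0.59 at 5 and 10 min, and limma adjusted p = 0.488 at 30 min) did not pass either. PECAM1 was not among the genes tested. Single libraries decided some of these: without 30 min replicate 1, EGR1 and FOS passed at 10 min (limma adjusted p = 0.0272 and 0.0241), without 10 min replicate 3 EGR1 passed at 10 min (0.0382), and without 10 min replicate 1 FN1 passed at 30 min (0.0131). FN1 also passed at 30 min under quantile normalization (0.0417) and with mitochondrial, ribosomal protein and histone genes removed (0.0478). With array weights, which count libraries that stand apart for less, KLF2 (limma adjusted p = 0.00232), FN1 (0.00408), EGR1 (0.0124) and NOS3 (0.0451) passed at 5 min, EGR1 (0.00207) and FOS (0.00224) at 10 min, and FN1 (0.000369), FOS (0.0118), EGR1 (0.0128) and VWF (0.018) at 30 min. At 5 min the highest adjusted p over all alternatives was 1.00 for each of these 4 genes, and at 30 min it was 0.761 (EGR1), 0.767 (FOS) and 0.859 (VWF), with the array weights giving the lowest. Over all alternatives the adjusted p lay between 0.00207 and 0.718 for EGR1 and 0.00224 and 0.716 for FOS at 10 min, and between 0.000369 and 0.743 for FN1 at 30 min. The log2 change at 10 min lay between −0.78 and 4.50 (EGR1) and between −0.81 and 4.18 (FOS). Its sign thus reversed under some alternative, without a call. EGR1 also reversed at 5 min (lowest −0.52), and EGR1 and FOS at 30 min (lowest −0.69 and −0.50). Without 30 min replicate 1 the 10 min changes stayed at 3.81 and 3.24, so only their error moved.

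Transcripts of SERPINB2 and of the mitochondrial genome differed between 5 and 10 min. SERPINB2 fell from 47.9 ± 6.80 to 4.44 ± 3.75 (SD, n = 3; log2 change −3.40 ± 0.48, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0137). Lower too by limma were DOK5 (−2.05 ± 0.34, adjusted p = 0.0367), SPATC1L (−2.90 ± 0.35, adjusted p = 0.00857) and LY96 (−2.78 ± 0.48, adjusted p = 0.0429). BCL2A1, a survival factor, went from 7.30 ± 3.26 to a listing of 0 in all 3 libraries at 10 min (limma adjusted p = 0.0367). MT-CYB (ENSG00000198727.2) rose from 904 ± 142 to 3451 ± 207 (1.94 ± 0.24, limma adjusted p = 0.00857). MT-ATP8 (2.11 ± 0.29, adjusted p = 0.012), MT-ND4 (2.26 ± 0.37, adjusted p = 0.0307), MT-CO1 (2.02 ± 0.33, adjusted p = 0.0307) and the nuclear ADA2 (1.99 ± 0.31, adjusted p = 0.0293) rose by limma. By that test 8 genes were higher and 11 lower at 10 min than at 5 min, 1690 had an unadjusted p under 0.05, and 2141 (19.8%, chance 10%) did not overlap. Calls numbered 0 and 0, 0 and 1, and 9 and 5 without 5 min replicates 1, 2 and 3. They numbered 5 and 6 without 0 min replicate 1 or 3, 5 and 17 without 10 min replicate 2, 44 and 42 without 10 min replicate 3, 26 and 30 without 30 min replicate 1, and 6 and 7 without 30 min replicate 2. None of the 10 genes named here by size stayed called in every fit that left out 1 library, and a fit of only the 5 and 10 min groups called 0 genes.

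As groups, the mitochondrial genes were higher at 10 than at 5 min (12 of 13 positive, median 1.94, 6 rising over all genes and 12 adjusted over the list alone; camera adjusted p = 1.55e-17, and 0.379 with an estimated correlation). Ribosomal protein genes (74 of 77 negative, median −0.54; 5.9e-15, and 0.637 with an estimated correlation), nuclear oxidative phosphorylation genes (63 of 74, median −0.27; 1.49e-05, and 0.637), endothelial identity genes (42 of 47, median −0.61; 2.97e-06, and 0.907) and p53 targets (26 of 32, median −0.44; 0.000595, and 0.662) were lower. Of these, 1 ribosomal gene (RPL36) fell over all genes, and adjusted over the list alone 3 ribosomal genes and 1 p53 target fell. Epithelial markers (median 0.84, camera adjusted p = 0.00189, and 0.379 with an estimated correlation) and NF-kB genes (0.50; 0.00849, and 0.851) were higher, and VEGF genes lower (−0.32; 0.0203, and 0.851). The fry test, which asks whether a list moves 1 way, called the mitochondrial genes and the NRF2 oxidative stress targets (median −0.20), both at adjusted p = 0.00855. The endothelial call was lost without 10 min replicate 1 (median −0.16, adjusted p = 0.125) and the VEGF call without that library (0.47), 30 min replicate 1 (0.0697) or 5 min replicate 2 (0.0597) or 3 (0.0563). Of these 8 list calls, 3 were kept with alpha-globin as a covariate, and the NF-kB and endothelial medians reversed without passing (−0.17 and 0.023, adjusted p = 0.685 and 0.874). These adjusted p lay, over all alternatives, between 2.98e-08 and 0.908 (endothelial), 0.000854 and 0.851 (NF-kB), and 0.00414 and 0.851 (VEGF).

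Between 10 and 30 min SPATC1L rose from 0.183 ± 0.317 to 15.5 ± 9.21 (SD, n = 3; log2 change 3.70 ± 0.35, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00129). It was the 1 gene called, with 942 at an unadjusted p under 0.05 and 1097 (10.2%, chance 10%) not overlapping. Without single libraries the calls reached 11 and 7 (10 min replicate 3), 8 and 2 (30 min replicate 1), 5 and 4 (10 min replicate 1), 4 and 0 (10 min replicate 2), 2 and 0 (5 min replicate 2) and 1 and 1 (30 min replicate 3). The digestive protease PRSS3 (3.11 ± 0.47, limma adjusted p = 0.0971) and FBN2 (−1.36) did not pass. PRSS3 passed without 10 min replicate 1 (limma adjusted p = 0.0175), 2 (0.0406) or 3 (0.0383), and FBN2 without 10 min replicate 1 (0.0273). Mitochondrial genes were lower at 30 min (median −0.78, camera adjusted p = 2.35e-05) and ribosomal genes (0.23; 0.000182), mitotic genes (0.28; 0.00426) and endothelial identity genes (0.36; 0.00722) higher, with NF-kB genes lower (−0.36; 0.0321), all at adjusted p = 0.899 with an estimated correlation. Under quantile normalization the mitochondrial and ribosomal calls were lost (−0.24 and 0.10, adjusted p = 0.389 and 0.126). The endothelial median was −0.13 (adjusted p = 0.3) without 10 min replicate 1, and the call was lost without 30 min replicate 2 (0.23) or 3 (0.321). The mitotic call was lost without 30 min replicate 2 (0.124). The NF-kB call was lost without 0 min replicate 2 (0.0553), 5 min replicate 1 (0.0537), 10 min replicate 1 (0.0842) or 30 min replicate 2 (0.328) or 3 (0.485). Of these 5 list calls, 2 were kept with alpha-globin as a covariate, and the NF-kB median (0.11, adjusted p = 0.895) and the endothelial test (0.875) reversed without passing. The lowest adjusted p over all alternatives was 4.59e-07 (mitochondrial), 8.38e-07 (ribosomal), 4.14e-05 (endothelial), 1.77e-05 (mitotic) and 5.43e-06 (NF-kB), and the highest 0.899.

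Between 5 and 30 min limma called 0 genes (smallest adjusted p = 0.639), with 532 at an unadjusted p under 0.05 and 1502 (13.9%, chance 10%) not overlapping; MT-ND5 was at 1.18 and MT-CYB at 1.06. Without 10 min replicate 1 limma called 1 gene higher. The mitochondrial genes were higher at 30 min in 13 of 13 genes (median 1.18, 12 rising adjusted over the list alone; camera adjusted p = 2.77e-18, and 0.506 with an estimated correlation). Ribosomal (median −0.28; camera adjusted p = 3.14e-09), p53 target (−0.38; 1.92e-06), oxidative phosphorylation (−0.15; 0.000356), VEGF (−0.26; 0.00088) and extracellular matrix genes (−0.17; 0.00237) were lower and mitotic genes higher (0.22; 0.000266), each at adjusted p = 0.578 with an estimated correlation. Endothelial identity genes (−0.25; camera adjusted p = 0.0042, and 0.791 with an estimated correlation), TGF-beta genes (−0.18; 0.0376, and 0.583) and Notch genes (−0.14; 0.0393, and 0.583) were lower. The endothelial call was lost without 5 min replicate 2 (0.0943) or 30 min replicate 1 (median 0.013, adjusted p = 0.725), and the mitotic call without 5 min replicate 3 (0.223). The Notch call was lost without 5 min replicate 2 (0.269) or 3 (0.168), 10 min replicate 1 (0.053) or 3 (0.0655), or 30 min replicate 1 (median 0.0034, adjusted p = 0.287) or 2 (0.0584). The TGF-beta call was lost without 5 min replicate 2 (0.231) or 3 (0.111) or 30 min replicate 1 (0.0698) or 2 (0.0863). Over all alternatives the adjusted p lay between 3.77e-05 and 0.990 (endothelial), 1.38e-16 and 0.593 (mitotic), 0.0155 and 0.719 (Notch), and 0.00314 and 0.822 (TGF-beta).

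Over all 4 groups, 26 genes differed by limma's F test with Benjamini-Hochberg adjustment, and 1432 had an unadjusted p under 0.05. The number was 3, 13 and 1 without 0 min replicates 1, 2 and 3, and 2, 6 and 2 without 5 min replicates 1, 2 and 3. It was 40, 15 and 58 without 10 min replicates 1, 2 and 3, and 83, 11 and 13 without 30 min replicates 1, 2 and 3. The calls at 5 and 30 min against 0 min shared 6 genes, SPATC1L and DOK5 higher and TGFB2, GPD2, FBN2 and C15orf38-AP3S2 lower. Independent lists would share 0.00509 higher and 0.00519 lower genes. Unchanged groups, simulated by reassigning the residuals of all 12 libraries, shared 0 on average over 100 runs. Unchanged groups give few calls by design, so that shared count could hardly differ from 0. The calls at 10 min shared C15orf38-AP3S2 with each of the other times (0.000648 and 0.000741 lower genes for independent lists). The fold changes over all tested genes correlated at 0.47 (5 and 10 min), 0.67 (5 and 30 min) and 0.69 (10 and 30 min), where simulated unchanged groups gave 0.50, 0.49 and 0.50. Their covariance was 0.150, 0.173 and 0.248 against 0.0941, 0.0924 and 0.0978 in the simulation, differences of 0.0560, 0.0808 and 0.150. The simulated 0 min groups drew on residuals of every library. The real 0 min libraries were more alike than those at 10 min (correlations 0.952 to 0.975 against 0.810 to 0.932). The simulated correlations and covariances may therefore overstate what shared 0 min libraries alone give. With 3 control libraries the controls could not be split, so part of the excess in shared calls may come from them. A batch or donor shared by the 5 and 30 min groups, which the simulation did not include, may also add to that excess.

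In the authors' deposited tables, every log2 fold change had the sign of the difference computed here (100% of 11319, 11985 and 11764 genes at 5, 10 and 30 min), and the p-values equalled those of a pooled-variance two-sample test within 1e-06. The authors' tables held 15, 10 and 6 genes at q under 0.05 (6 higher and 9 lower, 6 and 4, and 2 and 4). They held 2009, 1430 and 1247 at p under 0.05, and 1013, 968 and 713 of these with a fold of at least 1.5. Genes called in both the deposited tables and by limma numbered 4 at 5 min (C15orf38-AP3S2, FBN2, SMOC2 and SPATC1L) and 1 each at 10 and 30 min (C15orf38-AP3S2).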

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

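The tests of causes in this part were chosen only after the result was seen, while the comparisons between flow times had been fixed earlier. The change from 0 min differed between 10 and 5 min for 19 genes by limma's test of the difference with Benjamini-Hochberg adjustment, 8 of them higher and 11 lower at 10 min. Among them were SERPINB2, the plasminogen activator inhibitor, at −3.40, and the mitochondrial MT-CYB at 1.94. The change differed between 30 and 10 min for 1 gene, SPATC1L, which averaged an FPKM of 0.183 at 10 min and 15.5 at 30 min. A tested difference between groups is what set these genes apart, and donor as well as time may lie behind it. A fit of only the 5 and 10 min groups called 0 genes. Of the 10 genes named by size for these groups, 0 stayed called in every fit that left out 1 library. SPATC1L for 30 against 10 min stayed called in all 12 such fits.

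A test of the 5 and 30 min groups against the 0 and 10 min groups called 42 genes, and each of the other pairings of the 4 groups called 1 (1272 genes at an unadjusted p under 0.05, against 1476 and 761). How many of the genes called in the single comparisons are among the 42 was not counted. A trend with transcript length was excluded as the whole cause, since 39 genes were called with it removed, 35 of them shared, in a correction that moved 43.6% of genes by over 0.1 at 5 min. All 42 genes stayed called without the 2 libraries with the most alpha-globin (190 genes called). They also stayed called with alpha-globin as a covariate over all 12 libraries (115 called). This pairing set 0 min, with the least alpha-globin (FPKM up to 1.03), beside 10 min, with the most (up to 315). These fits could therefore hardly lower the count, and they do not exclude the alpha-globin signal of the flow libraries. A batch or donor shared by the 5 and 30 min groups may account for the 42 genes and cannot be told apart from time under flow, because every library of a group shares its time. The check for mixed-up samples showed that donors did differ between groups, as 6 libraries did not match the other 6 and 0 departed from most of their group. Which groups matched is not reported here. Time under flow itself would need an effect at 5 and 30 min that 10 min lacked, and no value here decides between time and a batch or donor.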

How the results depend on the processing

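The tests without both libraries with the most alpha-globin, with alpha-globin as a covariate and with the length trend removed were chosen only after the result was seen. Counts below are genes higher and lower by limma with Benjamini-Hochberg adjustment, which were 11 and 7 (5 against 0 min), 0 and 1 (10 against 0), 5 and 8 (30 against 0), 8 and 11 (10 against 5), 1 and 0 (30 against 10) and 0 and 0 (30 against 5), with 26 by the F test. Settings not named for a comparison left its count within 1.5 times. A similar count can hold other genes. The fit of only the groups compared called 13 genes at 30 min against 0 min, 5 of them among the 13 reported. Without replicate 1 of every group, 7 of 18 calls at 5 min and 5 of 14 at 30 min were among those reported. The cause of a move was not tested except where the setting itself removes libraries or genes.

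Of 2668 repeats of the values of named genes, 2059 kept their side of the threshold (39 of them, called in neither fit, changed sign), 505 lost the call, 104 gained it and 0 called values reversed. Of 1732 repeats for called gene lists, 1470 kept the call, 240 lost it and 22 reversed. Robust empirical Bayes moved no count by over 1.5 times. The same-sign share with the authors' tables was 100% with and without the filter. That share follows from the definition, since both fold changes are differences of mean log2(FPKM + 1), and says nothing on how stable the calls are.

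A pseudocount of 0.1 gave 5 higher at 5 min, 23 and 5 at 10 min, 5 higher for 10 against 5, 2 higher for 30 against 10 and 10 by the F test. A pseudocount of 0.01 gave 0 and 1 at 5 min, 25 and 5 at 10 min, 0 and 0 at 30 min, 3 higher for 10 against 5, 2 higher for 30 against 10 and 5 by the F test. No filter gave 3 higher at 30 min. A mean FPKM of at least 5 gave 4 lower at 5 min, 0 lower at 10 min, 3 lower at 30 min and 7 lower for 10 against 5, with fewer genes tested.

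Median-of-ratios rescaling gave 3 higher and 8 lower at 30 min. Rescaling to the same total gave 4 and 6 at 5 min, 11 and 7 at 10 min and 4 and 10 at 30 min, and moved the median of all genes to −0.27 at 10 min, −0.12 at 30 min, −0.20 for 10 against 5 and 0.11 for 30 against 10. Quantile normalization gave 12 and 12 at 5 min, 2 lower at 10 min, 14 and 25 at 30 min, 3 and 11 for 10 against 5 and 2 higher for 30 against 10, where 3 lists were called against 5. The calls shared with those reported were 10 of 18 at 5 min with the same total and 16 of 18 with quantile normalization. Removal of mitochondrial, ribosomal protein and histone genes moved the median of all genes to −0.12 at 5 min and gave 5 higher at 5 min, 15 lower at 30 min, 1 and 5 for 10 against 5, 2 lists for 30 against 10 and 16 by the F test.

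A fit of only the groups compared gave 33 and 31 at 5 min, 39 and 6 at 10 min and 0 and 0 for 10 against 5 (unadjusted p under 0.05 in 1690 genes in the fit of all groups); the F test has no such fit. Array weights, which count libraries that stand apart for less, gave 785 and 593 at 5 min, 719 and 336 at 10 min, 462 and 378 at 30 min, 341 and 223 for 10 against 5, 133 and 144 with 11 lists for 30 against 10, 3 and 7 for 30 against 5 and 1953 by the F test. All 18, 1 and 13 genes called against 0 min were among these. Among lists against 0 min, the ribosomal call at 10 min was lost with no filter (adjusted p = 0.0823), median-of-ratios rescaling (0.063), rescaling to the same total (0.433) and the length trend removed (0.0683), in a range of 5.07e-07 to 0.978 over all alternatives. The immediate early call at 5 min was lost with a mean FPKM of at least 5 (0.192), quantile normalization (0.0687) and array weights (0.107), in a range of 0.00257 to 0.815. Array weights ended the p53 (0.147; 0.00035 to 0.626) and cholesterol (0.253; 0.00369 to 0.697) calls at 30 min. The cholesterol call was also lost with a mean FPKM of at least 5 (0.0646), and the oxidative phosphorylation call at 30 min with the length trend removed (0.109; 4.25e-07 to 0.744). Quantile normalization ended the mitochondrial call at 10 min (0.872; 3.58e-09 to 0.872). Between flow times, the Notch call for 30 against 5 was lost in 8 of these settings (0.0504 to 0.164; 0.0155 to 0.719 over all alternatives), and the NF-kB call for 30 against 10 with a pseudocount of 0.01 (0.0602) or the gene groups removed (0.101; 5.43e-06 to 0.899). Array weights ended the VEGF call for 10 against 5 (0.193; 0.00414 to 0.851) and the endothelial call for 30 against 5 (0.177; 3.77e-05 to 0.990).

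Without both libraries with the most alpha-globin the counts were 143 and 107 at 5 min, 52 and 12 at 10 min, 31 and 37 at 30 min, 27 and 33 for 10 against 5, 17 and 13 with 8 lists for 30 against 10 and 132 by the F test, and every gene called against 0 min stayed called. EGR1 (2.96, limma adjusted p = 0.0389) and FOS (2.63, 0.0431) then passed at 10 min (0.00207 to 0.718 and 0.00224 to 0.716 over all alternatives), as did KLF2 at 5 min (1.46, 0.0392; 0.00232 to 1.00 over all alternatives) and FN1 at 5 min (−0.86, 0.0377; 0.00408 to 1.00) and 30 min (−1.23, 0.0202; 0.000369 to 0.743). The sign of EGR1 and FOS at 10 min was not stable over all alternatives (lowest log2 change −0.78 and −0.81). The list calls kept were 7 of 7 at 5 min, 11 of 13 at 10 min, 5 of 10 at 30 min, 6 of 8 for 10 against 5, 4 of 5 for 30 against 10 and 7 of 10 for 30 against 5. Lost at 30 min were the endothelial (median −0.07, adjusted p = 0.257; 1.98e-05 to 0.866 over all alternatives), p53 (0.257; 0.00035 to 0.626), cholesterol (0.483; 0.00369 to 0.697), oxidative phosphorylation (0.10; 4.25e-07 to 0.744) and epithelial (0.219; 0.000303 to 0.678) calls. For 30 against 5 the endothelial and Notch medians turned positive (0.013 and 0.0034, adjusted p = 0.662 and 0.268; 3.77e-05 to 0.990 and 0.0155 to 0.719), but not the test direction. With the length trend removed, 2 genes were higher at 30 min.

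With alpha-globin as a covariate there were 23 lower at 5 min, 0 and 1 at 30 min, 1 and 2 for 10 against 5 and 40 by the F test. Lists then called numbered 3 at 10 min, 6 at 30 min, 4 for 10 against 5 and 2 for 30 against 10, but the reported list calls kept in their direction were 3 of 7 at 5 min, 0 of 13 at 10 min, 1 of 10 at 30 min (ribosomal), 3 of 8 for 10 against 5, 2 of 5 for 30 against 10 and 7 of 10 for 30 against 5. The mitotic (adjusted p = 0.906; 3.81e-09 to 0.906), hypoxia (0.874; 0.00259 to 0.874) and fibroblast (0.874; 0.000317 to 0.874) calls at 5 min were lost. Medians that reversed at 10 min were endothelial 0.71, NF-kB −0.76, immediate early −0.43, Notch 0.11, VEGF 0.12, mitotic 0.25, p53 0.40, hypoxia −0.020, cholesterol −0.49, mitochondrial −0.54 and fibroblast −0.39. The endothelial, NF-kB and immediate early lists at 10 min and the endothelial list at 30 min then passed the threshold in the other direction (adjusted p = 0.000617, 0.000617, 0.0265 and 1.98e-05). Reversed too were immediate early genes at 5 min (−0.24), endothelial 0.81, p53 0.19, cholesterol −0.31, epithelial −0.33 and VEGF 0.14 (median only, not the test direction) at 30 min, NF-kB −0.17 and endothelial 0.023 for 10 against 5, and NF-kB 0.11 and endothelial (test direction; median 0.055) for 30 against 10. Alpha-globin was low in all 0 min libraries, so this covariate partly stands for flow itself.

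The camera test with an estimated correlation called 0 lists in all 6 comparisons (3, 2, 1, 3, 0 and 1 lists at an unadjusted p under 0.05, in the order above). Fry called 0 lists except 2 for 10 against 5 (6, 7, 5, 6, 1 and 1 lists at an unadjusted p under 0.05). At an unadjusted p of 0.01 the calls shared by 5 and 10, 5 and 30, and 10 and 30 min numbered 60, 132 and 97, where the adjusted test shared 1, 6 and 1.

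Leaving out 1 library, or 1 replicate number from every group, gave 0 to 28 higher and 0 to 20 lower at 5 min, 0 to 122 and 0 to 39 at 10 min, 0 to 27 and 0 to 42 at 30 min, 0 to 44 and 0 to 42 for 10 against 5, 0 to 11 and 0 to 7 for 30 against 10, 0 to 1 and 0 for 30 against 5, and 0 to 83 by the F test. Lists numbered 6 to 9, 10 to 13, 6 to 13, 6 to 10, 2 to 8 and 7 to 13. The endothelial median for 30 against 10 reversed without 10 min replicate 1 (−0.13, highest 0.72), and the ribosomal median at 10 min without replicate 3 of every group (−0.066, highest 0.33).

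The replicate numbers gave no clear pairing over all samples. Of 18 same-numbered pairs, 3 correlated over 0.1 in their deviations from the group means (−0.26 to 0.36). Only 4 of 12 libraries correlated best with their own number. Between 10 and 30 min, however, replicates 1 and 3 correlated at 0.36 and 0.32, so pairing between those times is not excluded. With the replicate number as a block the counts were 1 and 2 at 5 min, 2 and 5 at 30 min and 9 by the F test, and the 5 and 30 min calls shared 3 genes. The block with median-of-ratios rescaling gave 5 and 3 at 5 min, 2 and 5 at 30 min and 9 by the F test. All 53 list calls were kept under the block. With depth unknown, what it limits was not analysed here.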

Other observations

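The tests of dilution, of removed gene groups, of the range at 10 min, of transcript length and of variation at 0 min were chosen only after the result was seen. The tests of genes near 0, of a smaller mitochondrial share and of other splits were written down before their own results were seen. Alpha-globin, against which the genes near 0 were set, was taken into the alternatives only after the data were seen. Among matrix genes, the microfibril gene FBN2 fell at 5 and 30 min and the collagen COL4A1 at 30 min. The elastic fibre protein FBLN5 was at −2.17 and −2.33 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.18 and 0.118) and the collagen COL4A2 at −1.04 and −1.36 (limma adjusted p = 0.191 and 0.0605), none of them past the threshold. The 57 measured matrix genes went both ways: adjusted over the list alone 8 rose and 6 fell at 5 min and 7 rose and 10 fell at 30 min. Their median was 0.18, −0.28 and −0.01 at 5, 10 and 30 min, and at 10 min the mean was 0.03 where the median and the test were negative. The sulfatase SULF2, which trims heparan sulfate, was at −1.93 at 30 min (limma adjusted p = 0.0605), and the chemokine CCL2 at −2.88 (0.0819).

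Integrin and focal adhesion genes had medians of 0.04, 0.02 and 0.05 at 5, 10 and 30 min, and 0 of 51 changed over all genes or adjusted over the list alone at any of these times by limma (6, 2 and 8 at an unadjusted p under 0.05). The adaptor BCAR1 was at 1.07 and 0.92 at 5 and 30 min, and the laminin receptor subunit ITGA3 at 2.36 at 10 min (limma adjusted p = 0.22, 0.292 and 0.186). Flow-responsive endothelial genes had medians of 0.04, −0.33 and −0.05 (camera adjusted p = 0.104 at 10 min and 0.416 at 30 min). Adjusted over the list alone, 2 rose and 2 fell at 5 min, 2 fell at 10 min, and 1 rose and 4 fell at 30 min. The thioredoxin reductase TXNRD1 was at −1.07, −1.29 and −0.82, the thioredoxin inhibitor TXNIP at 2.00 and 2.04 at 10 and 30 min, and the vasoconstrictor EDN1 at −1.15 at 30 min. Interferon response genes had medians of 0.02, 0.12 and 0.19, with IFITM1 rising at 5 min and 3 genes rising adjusted over the list alone at 30 min. YAP and TAZ target genes had medians of −0.09, −0.29 and −0.12 (camera adjusted p = 0.084 at 30 min).

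Genes typical of other tissues appeared in the flow libraries, and were looked up after their values were seen. The synaptic SNAP25 was at an FPKM of 230 in 10 min replicate 1 and 74.2 in 30 min replicate 1, against 0.312, 0.558 and 0.736 at 0 min. The placental PSG1 was at 29.6 and 24.1 in the same libraries, and under 1 FPKM in every 0 min library. In 5 min replicate 3, SNAP25 and PSG1 were at 12.6 and 6.61. Leukocyte markers had medians of 0.61, 0.37 and 0.78 at 5, 10 and 30 min (camera adjusted p = 0.211, 0.939 and 0.36), and smooth muscle and pericyte markers had 2 measured genes, too few for the list test.

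Endothelial transcripts were lower and transcripts of other cell types higher in some flow libraries: of 636 genes near 0 at 0 min, 382, 149 and 58 reached an FPKM of 1 in the 10 min libraries, 322, 20 and 14 in the 30 min libraries and 12, 3 and 76 in the 5 min libraries. RNA of other cells or tissues may be the source, since this number followed alpha-globin over the 9 flow libraries (Spearman rho 0.983, exact permutation p = 4.96e-05, adjusted over 2 relations 9.92e-05; Pearson r 0.939, exact permutation p = 1.93e-05, adjusted 3.86e-05). Without 10 min replicate 1 and 30 min replicate 1, the farthest on alpha-globin, r was 0.941 (exact permutation p = 0.00139). Removal of mitochondrial, ribosomal protein and histone genes left the 10 min endothelial median at −0.79, which excludes their larger share as the cause. Dilution of endothelial transcripts by that RNA stays open (r −0.811, exact permutation p = 0.000537, adjusted 0.000537; rho −0.867, p = 0.00451, adjusted 0.00451): without those libraries r was similar (−0.741, rho −0.714) but did not pass 0.05 over 7 libraries (p = 0.0742 and 0.0881), and time under flow stays open as the endothelial median ranged over 1.64 among the 10 min libraries.

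Ribosomal protein transcripts were higher and mitochondrial transcripts lower at 5 min (camera adjusted p = 7.78e-30 and 4.07e-08 with a preset correlation, but 0.344 and 0.545 with an estimated correlation). A smaller mitochondrial share of the values was excluded as the whole cause, since the ribosomal median was 0.49 without those genes, from 0.67 with them (camera adjusted p = 5.78e-29, with a preset correlation). A trend with transcript length was excluded as the whole cause as well (median 0.55 with it removed, camera adjusted p = 1.94e-24). Variation between cultures at 0 min may contribute and stays open: 0 of the 0 min libraries lay inside the 5 min range on either measure, yet 0 min replicate 2 (0.35 ribosomal, −0.51 mitochondrial) lay close to its edge (0.36 and −0.69). Time under flow stays open and was not tested apart from donor or culture.

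Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For genes called, the real value and the highest other split were 18 and 0 (5 against 0 min), 1 and 0 (10 against 0), 13 and 1 (30 against 0), 19 and 1 (10 against 5), 1 and 749 (30 against 10) and 0 and 2 (30 against 5). The splits with as many genes, the real one included, numbered 1, 1, 1, 1, 6 and 10. For gene lists the real value and the highest other were 7 and 11, 13 and 12, 10 and 10, 8 and 9, 5 and 9, and 10 and 13, with 5, 1, 2, 4, 5 and 4 splits giving as many. Over 100 groupings of the 12 libraries for the F test, 4 gave as many as 26 genes, the real one included, and the highest other gave 507. That share is under 0.05, but it would exclude chance only for libraries that can be exchanged, and 6 libraries did not match the other 6, while 0 departed from most of their own group. The splits with 749 and 507 genes mix libraries of different times, and what sets their libraries apart was not tested.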
